A study of Amphimedon queenslandica with 124 samples.

How the data were processed

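The data are CEL-seq libraries of single individuals, collected individually at Heron Island on the Great Barrier Reef, staged by morphology and kept in RNAlater, per the labels' protocols. RNA was extracted with TRIzol, and polyadenylated RNA was amplified and sequenced by CEL-seq with multiplexing barcodes, per the labels' protocols. The submitters' processing notes name CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3. How these tools were set, the genome build, the annotation and any use of molecular identifiers are not given in the sources used here.

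The deposited table holds counts, as whole numbers per gene model and library, not normalized. The table was held only in part here. It ends within its last line, so that 36868 complete gene models were used. Of these, 3867 had no count in any library. All 124 columns belong to individuals of the series and 0 other columns were present. Gene models carry identifiers only. The reference table of gene names matched 0 of the identifiers, so no gene names are given and the 32 gene lists and the 25 lists of motifs and markers planned beforehand could not be applied.

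Stages were taken from the developmental stage in the labels, which was given for 123 individuals. Replicate numbers here follow the order of the embryo numbers within a stage and pair nothing across stages. The embryo numbers in the labels run from 1 to 124. The libraries numbered 101 to 124 stand apart in depth from the others of the stages from settlement onwards, but not from the embryo libraries. They hold 3 runs of 8 consecutive numbers with the same makeup of stages. Individuals of the same run showed little shared deviation from their stages, which was not tested. The median correlation of deviations from the stage means was 0.0177, 0.0126 and -0.00882 within the 3 runs and -0.0127 between runs. An effect of the runs is not excluded by these medians, and fits with a block for the runs are given below. No pair of libraries held identical values, and the closest pair of each stage differed by more than counting noise, with a chi-square per degree of freedom from 3.49 to 23.4.

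A minimum of 100000 counts per library was set before the data were examined, with the condition that no library would be left out if too large a share of them fell under it. Of the labelled libraries 30 (24.4%) fell under it, 22 at mat-formation, 3 at settlement, 3 at tent-pole-formation and 2 juveniles, and so all were kept. Tests without them, and tests within the libraries numbered 1 to 100 or 101 to 124, were added after the data were seen.

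Gene models were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a count minimum of 10 and a total of 15) between each pair of consecutive stages and between late ring and cleavage, in fits of the stages compared, and over all 14 stages in a single fit. All tests were two-sided, and a Benjamini-Hochberg adjusted p under 0.05 counted as called. Standard errors are those of the log2 fold change. The p-values measure the spread between individuals of a stage. DESeq2 1.42.0 was run as a second tool. CPM values are the deposited counts scaled to an equal total in every library. Ratios against 1 to 3 counts have an exact 95% interval, and ratios against a stage with no count use a floor of 3 counts over the stage. Such intervals and floors cover counting error only.

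Genes detected were counted after thinning each library to 100000 counts at random. Differences among stages were tested by permuting stage labels with 100000 resamples. The nearest neighbour of each library was the library with the highest Spearman correlation over 17221 expressed gene models, with a one-sided permutation test of the share of matches. These steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Values of gene groups are means of log2(CPM + 1) over the genes called in a comparison, in libraries with at least 100000 counts. A group's values at the stages that selected it are not independent of the selection. Numbers of genes shared by 2 comparisons were set against the product of the list lengths over the genes tested in both. Genes with low and high states were sought among the embryo libraries by the widest gap in sorted CPM that left at least 5 libraries on each side.

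The rule for named genes, fixed before the data were examined, takes the highest and lowest log2 fold changes among genes with an adjusted p under 0.05 and a mean of at least 50 CPM in the higher stage over 6 main comparisons, and, with no names, at most 2 gene models that rose and 2 that fell. Any other gene model is said to have been chosen after its values were seen.

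The edgeR test was checked on simulated counts for each comparison, with 200 genes changed by known folds in both directions. In the comparisons of at least 7 individuals per stage, 92.4% to 100% of genes changed 8-fold were recovered, 44.8% to 82.1% of those changed 4-fold and 2.99% to 25.4% of those changed 2-fold. The shares for 8-fold changes were 34.8% for chamber-formation against mat-formation, 54.5% for tent-pole-formation against chamber-formation, 16.7% for juvenile against tent-pole-formation and 27.3% for adult against juvenile. Unchanged genes made up 16.2%, 2.27%, 12.5% and 11.5% of the calls in these comparisons, from 6, 1, 2 and 3 such genes. With at least 7 individuals per stage the share was 0.901% to 6.30%. Calls in the small comparisons may therefore exceed the nominal share of false calls.

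The alternatives were DESeq2's size factors, no filter on low counts, DESeq2's Wald test, 1 fit of all stages, at least 500000 counts per library, a log2 fold change of at least 1, the log10 library total as a covariate, 3 libraries per stage in 10 draws, and leaving out each replicate of a stage of 2 to 5 individuals. The alternatives added after the data were seen were at least 100000 counts per library, the libraries of either number set, a block for the runs of numbers, the number set as a covariate in the fit of all stages, each library left out of the fold of a named gene, and splits of the libraries within a number set.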

Results

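The transcriptomes of 124 single individuals of the demosponge Amphimedon queenslandica were measured by CEL-seq, a barcoded method that counts the 3' ends of polyadenylated RNA. The individuals span development from cleaving embryos to adults. Embryos of this sponge develop in brood chambers of the mother, and the embryo stages from cloud to late ring are named for the pigment pattern at the posterior pole. The larva swims freely, settles, and turns through mat, chamber and tent-pole forms into a juvenile. A stage label was given for 123 individuals in 14 stages. There were 7 each at cleavage, brown, cloud, spot, late spot, ring and late ring, 13 free-swimming larvae, 10 at settlement, 34 at mat-formation, 3 at chamber-formation, 6 at tent-pole-formation, 5 juveniles and 3 adults. The count table holds 36868 complete gene models, and 33001 of them had at least 1 count. Total counts per library ran from 1158 to 3059409, with a median of 643731.

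Depth was uneven along the series. All 62 embryo and free-swimming larval libraries had more than 100000 counts, with stage medians from 619363 at cleavage to 1454224 at cloud. After settlement the libraries fell into sets that follow the embryo numbers in the labels. The 24 libraries numbered 101 to 124 hold stages from settlement to adult at stage medians of 1087643 to 1466051 counts. The 25 mat-formation libraries numbered 1 to 100 had a median of 32170 counts. The chamber-formation and adult individuals were all numbered 101 to 124. Comparisons between stages from settlement onwards are therefore given over all libraries and again within the libraries numbered 101 to 124. Settlement against free-swimming larvae, which were all numbered 1 to 100, is given again within the libraries numbered 1 to 100.

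Fewer genes were detected in embryos as brooding went on, and the numbers after the larva went with the number set as well as the stage. At an equal depth of 100000 counts, 8006 ± 1659 (SD, n = 7) gene models were detected at cleavage, 7423 ± 739.6 (n = 7) at brown and 6140 ± 288 (n = 7) at late ring. The number was 6854 ± 934 (n = 13) in free-swimming larvae, 8227 ± 2063 (n = 7) at settlement and 8014 ± 952 (n = 12) at mat-formation. It was 8735 ± 202 (n = 3) at chamber-formation, 8837 ± 306 (n = 3) at tent-pole-formation, 8926 ± 39.4 (n = 3) in juveniles and 9480 ± 324 (n = 3) in adults. The stages differed by more than their spread in a permutation test with 100000 resamples over 93 libraries (p = 1e-05, the smallest that these permutations can give). The number was 7848 ± 383 (n = 3) at settlement and 8425 ± 387 (n = 9) at mat-formation within the libraries numbered 101 to 124, and 8512 ± 2857 (n = 4) and 6782 ± 1162 (n = 3) within those numbered 1 to 100. All libraries from chamber-formation to adult that entered this count were numbered 101 to 124. Against embryos and larvae, all numbered 1 to 100, stage and number set therefore cannot be told apart. Within the libraries numbered 101 to 124 the set is constant, and the mean rose from 7848 at settlement to 9480 in adults. Without thinning, the difference among stages gave a permutation p of 0.007 over 123 libraries, and total counts differed among stages as well (permutation p = 1e-05).

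**Figure D1:**
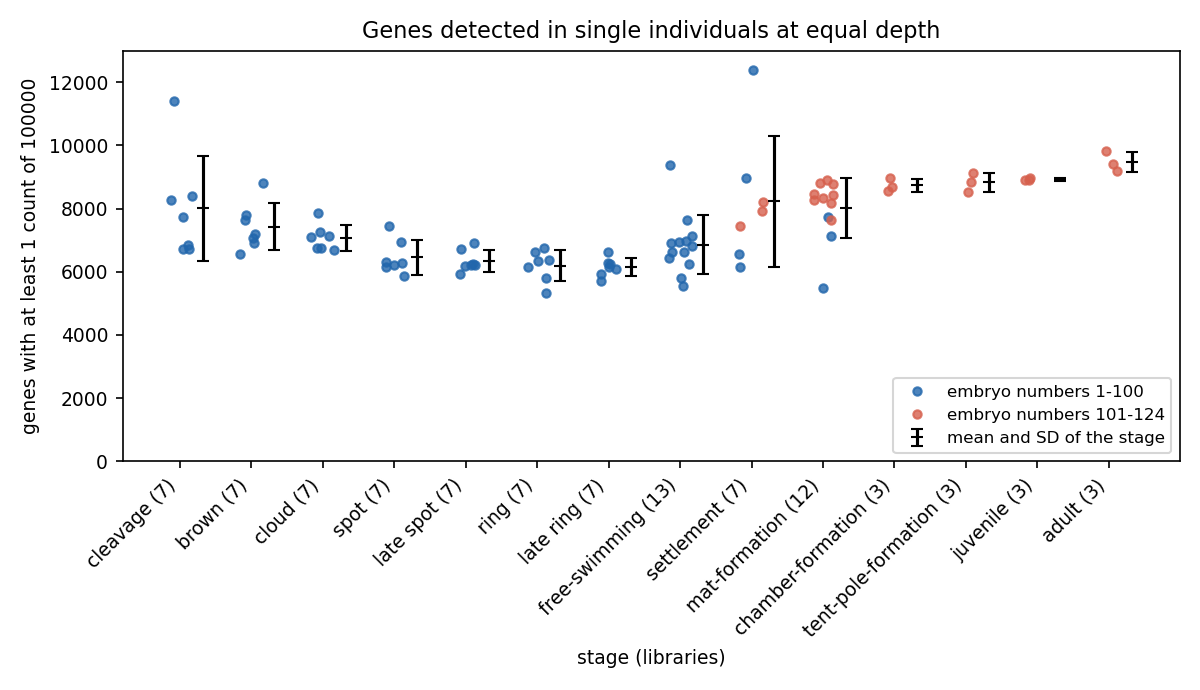
Gene models with at least 1 count after each library was thinned to 100000 counts, by stage, with 1 point per individual coloured by its embryo number, and the mean and SD of each stage as bars. The means fall from 8006 at cleavage to 6140 at late ring and reach 9480 in adults.

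Single individuals grouped by morphological stage. The library with the highest rank correlation to a given library came from the same stage in 68 of 123 cases (55.3%, against 11.5% with stage labels permuted) and from the same or an adjacent stage in 110 of 123 (89.4%, against 25.1%). Both shares gave a one-sided permutation p of 1e-05, the smallest that 100000 resamples can give. All 7 cleavage, 7 brown, 7 cloud and 7 late ring libraries, all 13 free-swimming larvae and all 3 adults were nearest to a library of their own or an adjacent stage. Ring was the stage with the fewest such matches, in 3 of 7 libraries. None of the 6 tent-pole individuals was nearest to another tent-pole individual. Among the 93 libraries with at least 100000 counts, the share of matches to the same stage was 65.6% (permutation p = 1e-05).

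Over those 93 libraries, chamber-formation, tent-pole-formation and juvenile individuals were nearly as similar across stages as within them. The median rank correlation was 0.874 between chamber-formation and tent-pole-formation, 0.877 between chamber-formation and juveniles, and 0.870 within chamber-formation, against 0.905 within juveniles. Among the embryo stages cleavage had the lowest median within the stage, at 0.638, against 0.707 with brown. This went with depth. Cleavage replicates 2, 3 and 4, at 214376 to 325307 counts, had medians of 0.560 to 0.663 with their stage. The deeper cleavage libraries had 0.712 to 0.736. No correlation within a stage was computed at equal depth. Settlement stage libraries reached at most 0.680 with any other stage, at mat-formation, and 0.4997 within the stage. Within settlement the median was 0.869 among the 3 libraries numbered 101 to 124, 0.578 between the number sets and 0.447 among the 4 numbered 1 to 100, and single pairs ran from 0.284 to 0.873. These correlations are across 17221 gene models, which are not independent replicates.

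**Figure D2:**
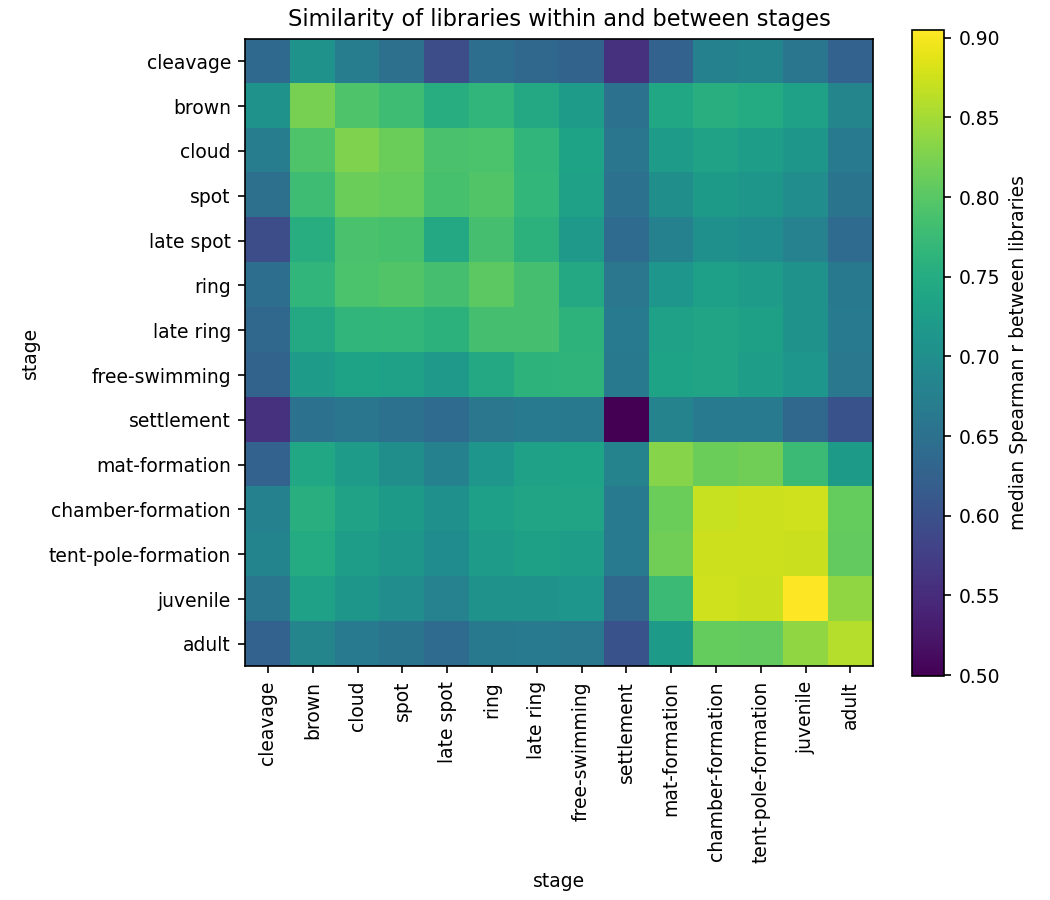
Median Spearman correlation between libraries of each pair of the 14 stages, and within each stage on the diagonal, over libraries with at least 100000 counts. Colour gives the correlation. Chamber-formation, tent-pole-formation and juvenile form a block of high values, and settlement has the lowest values.

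Most expressed genes were called as different among the stages, but the test also called many genes with stage labels permuted. Of 17221 gene models tested over all stages, 12984 (75.4%) were called at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. With stage labels permuted only within each number set, the same test called a median of 5302 genes and at most 6582. With labels permuted over all libraries it called up to 5260. The adjusted p of this test therefore did not hold its nominal level, and 75.4% does not measure the share of genes that differ. With the number set as a covariate 14540 (84.4%) were called, in a fit for which no labels were permuted. Mean expression of the 12984 genes was highest most often in adults (2663 genes) and at settlement (2180). Next came cleavage (1269), mat-formation (1162) and chamber-formation (1119). Adults and chamber-formation had 3 libraries each, all in the same number set, and mat-formation had 34. Effects of the number of libraries and of the number set on this ranking were not separated from stage. Few genes were highest at spot (414), late spot (309), ring (184) or late ring (245). Without libraries under 100000 counts, which changes the genes tested as well, 10106 of 13422 gene models were called. Of these, 8.32% were highest at settlement, against 16.8% over all libraries, 6.31% at mat-formation, against 8.95%, and 11.9% in juveniles, against 6.32%. With the median in place of the mean, 863 genes were highest at settlement and 143 at mat-formation, and the tent-pole number went from 585 to 295. By the median 1644 of the 12984 genes had no highest stage. Of the others, 7280 (64.2%) had the same highest stage as by the mean.

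From cleavage to brown, about as many genes rose as fell. Of 6173 gene models tested, 689 rose and 680 fell (7 against 7 individuals). The median log2 fold change was 2.04 among the genes that rose and -2.18 among those that fell, and 177 genes rose and 153 fell by at least 8-fold. The genes that fell went from a mean log2(CPM + 1) of 6.97 ± 0.37 (SD, n = 7) at cleavage to 4.94 ± 0.49 at brown and 4.28 ± 0.33 at ring. In stages not used to select them, they stood at 5.62 ± 0.07 (n = 3) at chamber-formation and 5.97 ± 0.08 (n = 3) in adults. All chamber-formation and adult libraries belong to a different number set from the embryo libraries. Whether these genes returned after the embryo stages therefore cannot be told apart from the number set. The genes that rose went from 4.14 ± 0.75 at cleavage to 6.80 ± 0.53 at brown, reached 7.39 ± 0.22 (n = 7) at cloud and stood at 5.45 ± 0.64 (n = 7) at late ring. With the library total as a covariate 809 genes passed the test, with 3 libraries per stage a median of 446 over 10 draws, and in one fit of all stages 664 rose and 964 fell.

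A single gene model dominated the cleavage transcriptome. Aqu2.1.20225_001 was the most abundant in all 7 cleavage libraries, with 7.84% ± 3.93 (SD, n = 7) of all counts, and took 0.637% ± 0.611 (n = 7) at brown and 0.035% ± 0.069 (n = 7) at late ring. Its log2 fold change from cleavage to late ring was -7.80 (SE 1.16, adjusted p = 2.74e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Pooled over libraries it was 143.8-fold lower at late ring, and 643-fold lower without late ring replicate 6. A different gene model took over later. Aqu2.1.29497_001 held 1.00% ± 0.233 (n = 7) of counts at cleavage, 4.07% ± 2.12 at late spot, 13.8% ± 5.81 at ring, 13.5% ± 4.82 at late ring and 12.3% ± 3.87 (n = 13) in free-swimming larvae. It was the most abundant in all 7 ring and all 7 late ring libraries and in 11 of 13 larvae. At settlement its share was 3.02% ± 1.70 (n = 10), and in adults 1.42% ± 0.157 (n = 3). From cleavage to late ring it rose by 3.98 on the log2 scale (SE 0.543, adjusted p = 1.12e-05, edgeR with Benjamini-Hochberg adjustment). Both were chosen after their values were seen.

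Between cleavage and late ring, the start and the end of brooded development, 1060 gene models rose and 849 fell of 4529 tested (7 against 7 individuals). The median log2 fold change was 2.62 among those that rose and -1.82 among those that fell, and 438 rose and 149 fell by at least 8-fold. Aqu2.1.00630_001 had the highest fold change that met the rule for named genes. It went from 0.614 ± 1.18 CPM (SD, n = 7) at cleavage to 591 ± 438 CPM (n = 7) at late ring (log2 fold change 10.13, SE 0.979, adjusted p = 3.52e-07, edgeR with Benjamini-Hochberg adjustment). Pooled over libraries, 3 counts at cleavage stood against 3783 at late ring, a ratio of 1005 with a 95% counting interval of 344 to 4878. Its mean was 11.9 ± 18.6 CPM (n = 7) at late spot, 220.3 ± 407 CPM (n = 7) at ring, 96.9 ± 57.8 CPM (n = 13) in free-swimming larvae and 0.489 ± 0.462 CPM (n = 3) in adults. Aqu2.1.35029_001 fell from 128 ± 113 CPM (n = 7) at cleavage to no count in the 7 late ring libraries, at least 162-fold lower by a floor of 3 counts over the stage (adjusted p = 2.9e-05, edgeR with Benjamini-Hochberg adjustment). It stood at 39.2 ± 16.4 CPM (n = 3) in adults. Without a filter on low counts 3137 genes passed the test, with 3 libraries per stage a median of 1140.5, and in one fit of all stages 1493 rose and 1778 fell.

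In fits of each pair of neighbouring stages over all libraries, the step from brown to cloud changed the largest number of genes. It did so as well with DESeq2's size factors (1686) and DESeq2's Wald test (2060). The same held with the library total as a covariate (1537) and a log2 fold change of at least 1 (1495). With at least 500000 counts per library the step was again the largest (1693). Every brown and cloud library passed that minimum, so at this step that fit repeats the main fit. In the other alternatives run at this step, brown to cloud did not change the largest number. Of 6363 gene models tested, 833 rose and 860 fell (7 against 7 individuals), with median log2 fold changes of 1.73 and -1.38. Few of these changes were large, with 64 genes up and 20 down by at least 8-fold. The genes that rose went from a mean log2(CPM + 1) of 5.07 ± 0.68 (SD, n = 7) at brown to 6.95 ± 0.14 (n = 7) at cloud, and were at 3.75 ± 0.44 (n = 7) at cleavage. They stayed at 6.38 ± 0.25 (n = 7) at ring and were at 4.42 ± 0.53 (n = 12) at mat-formation. In one fit of all stages 365 genes passed the test, fewer than at settlement (2756), brown (1628), mat-formation (745) and free-swimming (554). Without a filter on low counts 1522 passed, fewer than at settlement (3292) and brown (1850), and with 3 libraries per stage the median was 148.5, against 446 at brown, 282 at adult and 256.5 at chamber-formation.

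From cloud through ring, fewer genes were called per step than from brown to cloud. From cloud to spot 109 gene models rose and 128 fell of 5737 tested. From spot to late spot and from late spot to ring, edgeR's quasi-likelihood test called 0 of 4785 and 0 of 4929 gene models, with 428 and 433 at an unadjusted p under 0.05 where 239 and 246 would come by chance. DESeq2 called 65 and 54 genes at these steps, and across both steps together edgeR called 374 genes in ring against spot. In spot against late spot, the 95% interval of the fold change lay within 4-fold for 90.1% of genes and within 2-fold for 33.4%. In simulated counts, 7.46% of genes changed 2-fold were recovered from spot to late spot and 16.4% from late spot to ring, so changes of that size would mostly have been missed. In spot against cloud, DESeq2 called 447 genes, the test without a filter on low counts 419, one fit of all stages 37 and the draws of 3 libraries per stage a median of 3.

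From ring to late ring edgeR called genes again, and 291 gene models rose and 205 fell of 4817 tested (7 against 7 individuals). Those that fell formed a group that was high only in the middle of brooding among the embryo stages. Their mean log2(CPM + 1) was 3.64 ± 0.68 (SD, n = 7) at cleavage, 7.62 ± 0.13 (n = 7) at cloud, 7.83 ± 0.10 (n = 7) at spot, 7.25 ± 0.32 (n = 7) at ring and 4.96 ± 0.92 (n = 7) at late ring. Among the genes called in both steps, which share no libraries, 111 rose from cleavage to brown and fell from ring to late ring, where 24.1 would be common to independent lists. The genes that rose from ring to late ring went from 5.22 ± 0.45 to 7.28 ± 0.52, and were at 7.47 ± 0.15 (n = 13) in free-swimming larvae. DESeq2 called 790 genes at this step and one fit of all stages called 156. With 3 libraries per stage edgeR called a median of 0 over 10 draws, from 0 to 195, with a median of 713.5 at an unadjusted p under 0.05.

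The free-swimming larvae differed from late ring embryos mostly by genes that fell. Of 4896 gene models tested, 157 rose and 414 fell (13 against 7 individuals), with median log2 fold changes of 1.41 and -1.51. Those that fell had been high from cloud onwards, at a mean log2(CPM + 1) of 7.41 ± 0.07 (n = 7) at cloud and 7.74 ± 0.21 (n = 7) at ring, and went from 7.31 ± 0.78 (n = 7) at late ring to 6.02 ± 0.21 (n = 13) in larvae. The genes that rose went from 4.27 ± 0.19 (n = 7) to 6.08 ± 0.29 (n = 13) and were at 5.58 ± 0.14 (n = 3) in adults. With the library total as a covariate 305 genes passed the test, without a filter on low counts 865, and with at least 500000 counts per library 359. With 3 libraries per stage edgeR called a median of 0 over 10 draws, from 0 to 149, with a median of 640 at an unadjusted p under 0.05.

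**Figure D3:**
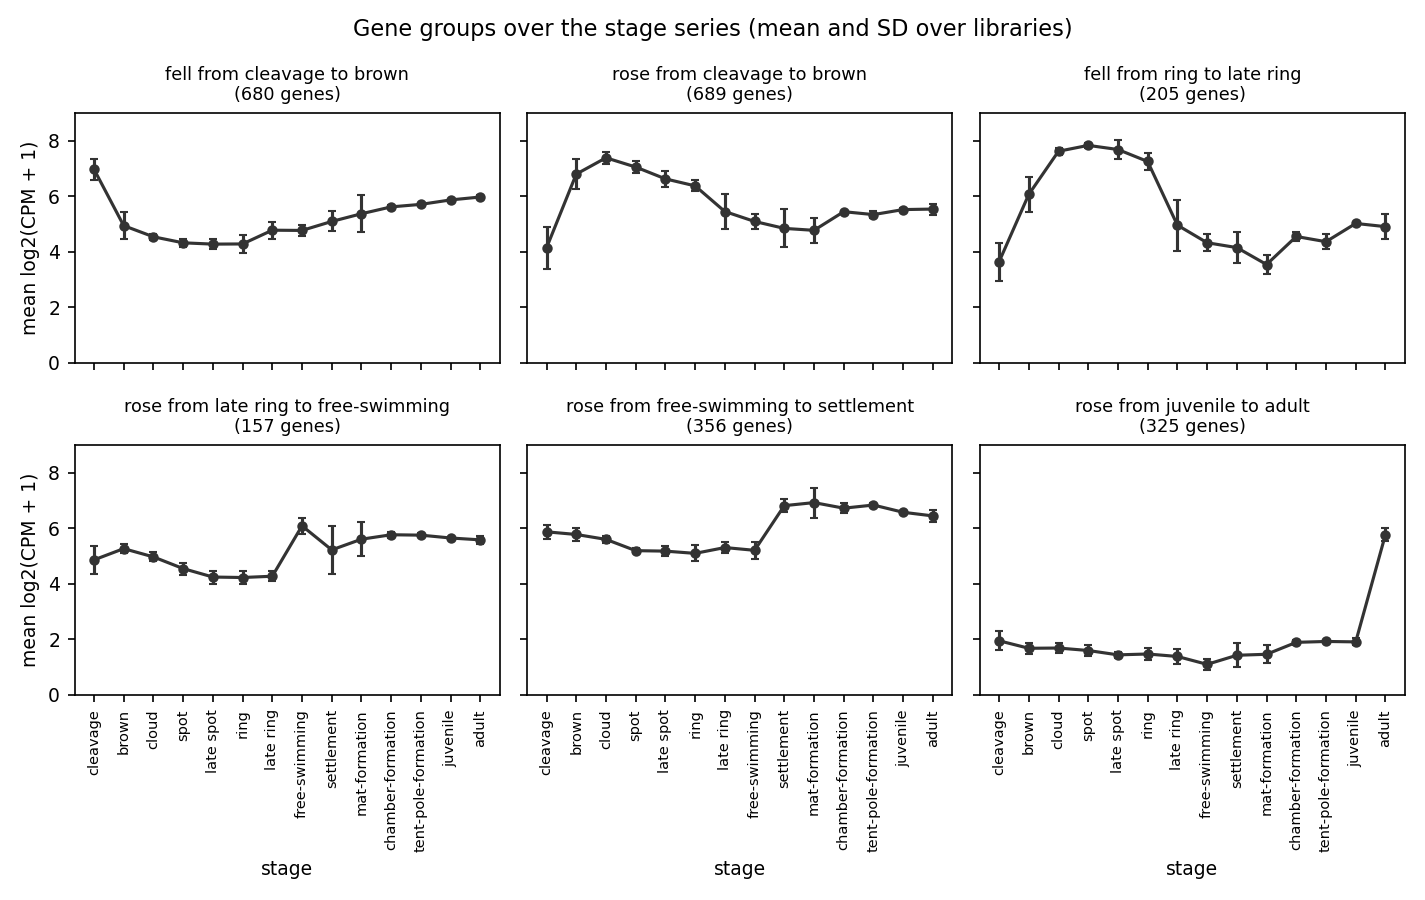
Mean log2(CPM + 1) of 6 gene groups along the 14 stages, with points at the mean and bars at the SD over libraries with at least 100000 counts. Each group was selected for its change between the pair of stages named above its panel. The genes that fell from cleavage to brown are at 6.97 at cleavage, 4.28 at ring and 5.97 in adults. Adult and embryo libraries belong to different number sets. The genes that rose from juvenile to adult are near 1 to 2 at every other stage.

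At settlement, when the larva attaches to the substrate, larval genes fell and another group rose. Of 4365 gene models tested, 356 rose and 393 fell (10 against 13 individuals), with median log2 fold changes of 1.83 and -1.46. The genes that rose went from a mean log2(CPM + 1) of 5.20 ± 0.31 (SD, n = 13) in larvae to 6.81 ± 0.23 (n = 7) at settlement, and were at 6.92 ± 0.54 (n = 12) at mat-formation and 6.44 ± 0.21 (n = 3) in adults. Larvae were all numbered 1 to 100 and adults all 101 to 124, and the settlement and mat-formation values mix both number sets. Whether the group stayed up after settlement therefore cannot be told apart from the number set. The genes that fell had climbed from 5.30 ± 0.34 (n = 7) at cleavage to 7.79 ± 0.17 (n = 13) in larvae and were at 5.94 ± 1.16 (n = 7) at settlement. Within the libraries numbered 1 to 100, 439 genes rose and 537 fell, and 596 of these 976 were among the 749 genes called over all libraries, all in the same direction. Without a filter on low counts 2688 genes rose and 604 fell, in one fit of all stages 2283 rose and 473 fell, and DESeq2 called 608 up and 467 down. With at least 500000 counts per library 331 genes changed, and with 3 libraries per stage a median of 12.

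**Figure D4:**
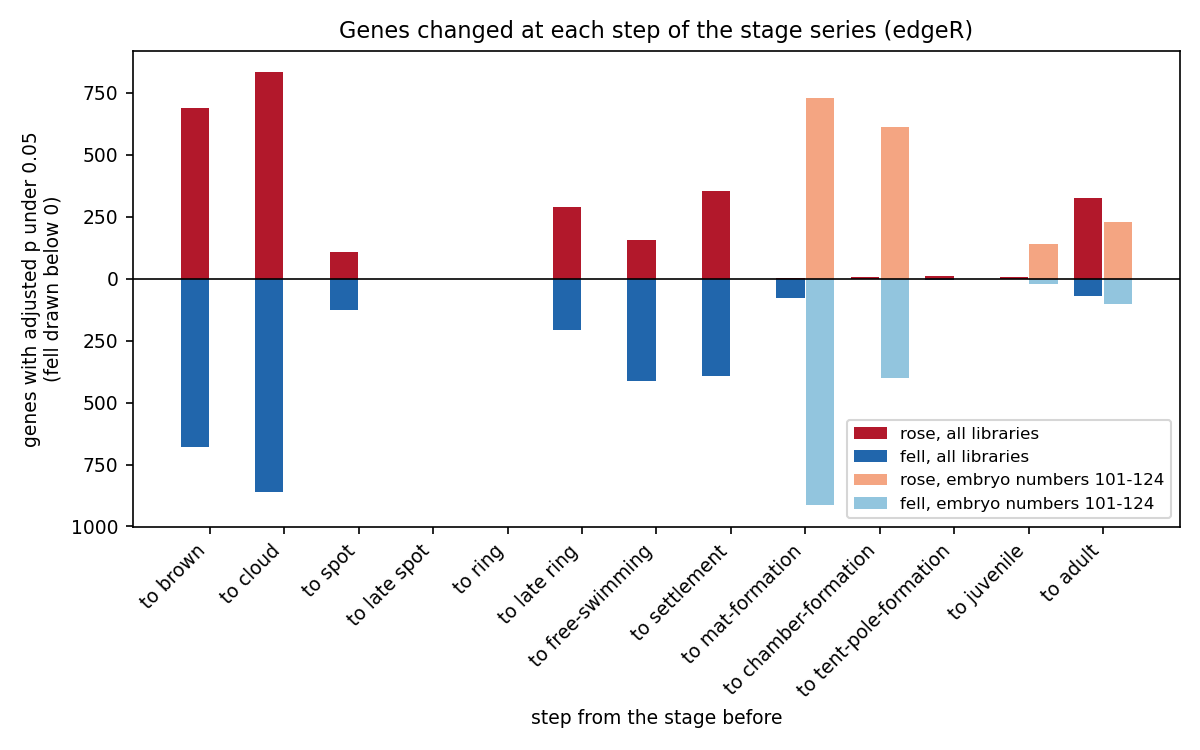
Number of gene models that rose (above 0) or fell (below 0) from each stage to the next at an adjusted p under 0.05 in edgeR, over all libraries and within the libraries numbered 101 to 124. Brown to cloud has 833 and 860 genes, spot to late spot and late spot to ring have 0, and settlement to mat-formation has 731 and 914 within the libraries numbered 101 to 124.

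The change from settlement to mat-formation depended on which individuals were compared. Over all libraries 2 gene models rose and 78 fell of 1480 tested (34 against 10 individuals). Within the libraries numbered 101 to 124, 731 rose and 914 fell of 8599 tested (9 against 3), with median log2 fold changes of 1.61 and -1.83, and 124 rose and 179 fell by at least 8-fold. Of the 80 genes called over all libraries, 67 were called in that set as well, 65 of them in the same direction. In the libraries numbered 1 to 100 alone, 10 genes fell. Aqu2.1.31172_001, which rose over all libraries, went from 77.4 ± 124 CPM (SD, n = 10) to 1319 ± 2091 CPM (n = 34), a log2 fold change of 3.82 (SE 1.14, adjusted p = 0.032, edgeR with Benjamini-Hochberg adjustment). It had a count in 22 of 34 mat-formation libraries. Those without one were all numbered 1 to 100, while each library numbered 101 to 124 had 2220 to 10013 counts of it. It was at 3042 ± 1106 CPM (n = 3) at chamber-formation, 274 ± 292 CPM (n = 3) in adults and at most 0.997 ± 1.43 CPM (n = 7) in any embryo stage. Within the libraries numbered 101 to 124 its log2 fold change was 5.84 (adjusted p = 2.65e-06), and pooled over all libraries it was 59.3-fold higher. Its adjusted p was 0.0533 with the library total as a covariate and 0.0567 without a filter on low counts, the highest over its alternatives. Aqu2.1.23732_001, the other gene that rose (log2 fold change 2.68, SE 0.831, adjusted p = 0.0419, edgeR with Benjamini-Hochberg adjustment), had a log2 fold change of 0.55 and an adjusted p of 0.559 in edgeR within the libraries numbered 101 to 124. Both genes are named because they were the only ones that rose, and were chosen after their values were seen.

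The group of genes that fell from settlement to mat-formation in the libraries numbered 101 to 124 had risen through brooding. Its mean log2(CPM + 1) was 4.06 ± 0.38 (SD, n = 7) at cleavage, 5.64 ± 0.11 (n = 7) at cloud, 6.09 ± 0.16 (n = 7) at late ring and 6.21 ± 0.23 (n = 13) in larvae, stages not used to select it. It was at 5.08 ± 0.16 (n = 3) in adults. Between comparisons that share no libraries, 480 genes rose from cleavage to late ring and fell from settlement to mat-formation, against 171 common to independent lists, and 28 rose in both, against 104.

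At chamber-formation, when the chambers of flagellated feeding cells form, the balance of genes up and down depended on the tool. Over all libraries 9 gene models rose and 0 fell of 2965 tested (3 against 34 individuals), with 463 at an unadjusted p under 0.05 in edgeR, while DESeq2 called 2 up and 551 down. Among the libraries numbered 101 to 124, 613 rose and 399 fell of 8809 tested (3 against 9), with median log2 fold changes of 2.30 and -1.80, and 193 rose and 73 fell by at least 8-fold. All 9 genes called over all libraries were called in that set in the same direction. Without chamber-formation replicate 1, or without replicate 2, edgeR called 3 genes over all libraries.

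The tent-pole stage was not distinguished from chamber-formation in the deep libraries. Over all libraries 13 gene models rose and 4 fell of 7198 tested (6 against 3 individuals). Within the libraries numbered 101 to 124 edgeR called 0 of 7958 gene models (3 against 3), with 453 at an unadjusted p under 0.05, and DESeq2 called 2 over all libraries. The 3 tent-pole libraries numbered 1 to 100 had 16097 to 31360 counts. Without chamber-formation replicate 1 edgeR called 8 genes, without replicate 2 it called 0 and without replicate 3 it called 27.

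From tent-pole-formation to juvenile, the number of genes called depended on the fit. Over all libraries 9 gene models rose and 0 fell of 6180 tested (5 against 6 individuals), with 338 at an unadjusted p under 0.05 in edgeR, while DESeq2 called 27 up and 3 down. With the library total as a covariate edgeR called 0 genes, with 540 at an unadjusted p under 0.05, and without a filter on low counts 56 rose and 76 fell. Among those numbered 101 to 124, 141 rose and 21 fell of 8390 tested (3 against 3), with a median log2 fold change of 2.81 among those that rose, and with a block for the runs of numbers 9 rose and 1 fell. Without that block, 48 genes in the set rose both from mat-formation to chamber-formation and from tent-pole-formation to juvenile, 2 comparisons that share no libraries, against 6.61 common to independent lists. Without juvenile replicate 1 edgeR called 42 genes over all libraries, without replicate 2 it called 75, and without replicate 4 or replicate 5 it called 5.

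Adults had a large set of genes that were scarcely expressed at any earlier stage. Of 8749 gene models tested, 325 rose and 70 fell from juvenile to adult (3 against 5 individuals), and 296 rose and 66 fell by at least 8-fold. The median log2 fold change was 4.33 among the genes that rose and -4.09 among those that fell, or 4.31 and -4.07 with the genes at 0 in every library of a stage set to their bound. The genes that rose were at a mean log2(CPM + 1) of 5.77 ± 0.22 (SD, n = 3) in adults, 1.90 ± 0.13 (n = 3) in juveniles and between 1.09 ± 0.19 (n = 13) and 1.94 ± 0.35 (n = 7) at the other stages. The genes that fell were at 5.18 ± 0.16 (n = 3) in juveniles, 4.16 ± 0.09 (n = 3) at chamber-formation and 1.71 ± 0.08 (n = 3) in adults. With only those numbered 101 to 124 compared, 230 genes rose and 103 fell, and 239 were among the 395 genes called over all libraries, all in the same direction. With a block for the runs of numbers in that set, 192 genes were called. Over all libraries one fit of all stages called 170 genes, the test without a filter on low counts 865, and edgeR without adult replicate 2 called 617.

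Aqu2.1.28757_001 had 100.3 ± 121 CPM (SD, n = 3) in adults, with values from 14.1 to 239 CPM, and no count in 5 juveniles, at least 191-fold higher by a floor of 3 counts over the stage (adjusted p = 7.8e-05, edgeR with Benjamini-Hochberg adjustment). Adult replicate 1 held 437 of its 504 counts. Without that library the bound was 47.1-fold and the log2 fold change 7.90 in place of 9.78, and without juvenile replicate 4 the bound was 119.8-fold. Its adjusted p in edgeR was 0.052 within the libraries numbered 101 to 124. Aqu2.1.35519_001 had 75.5 ± 79.9 CPM (n = 5) in juveniles, with counts in 3 of 5, and no count in 3 adults, at least 78.8-fold lower by the same floor (adjusted p = 0.000941, edgeR with Benjamini-Hochberg adjustment). This bound was 42.6-fold without adult replicate 1, 44.7-fold without juvenile replicate 5 and 125.7-fold without juvenile replicate 4. Its mean was at most 2.58 ± 2.25 CPM (n = 3) at any other stage, at chamber-formation. Its adjusted p was 0.108 in edgeR with the library total as a covariate and 0.0994 in DESeq2.

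A small set of abundant gene models took separate low and high states in single embryos of every embryo stage. Over the 49 embryo libraries, Aqu2.1.35836_001 was at 20.7 to 183 CPM in 14 libraries and at 1567 to 64470 CPM in the other 35, with no library between. Aqu2.1.33181_001 split the libraries in the same way, at 22.0 to 197 CPM in the same 14 and 1225 to 44880 CPM in the other 35. Aqu2.1.30620_001 was at 126 to 1867 CPM in those 14 libraries and ring replicate 5, and at 9180 to 100200 CPM in the remaining libraries. Aqu2.1.23821_001 had the opposite pattern, at 387 to 3823 CPM in the 14 libraries and 0 to 114 CPM in the other 35. The 14 libraries were 2 of 7 at cleavage, 1 at brown, 4 at cloud, 3 at spot, 2 at late spot, 1 at ring and 1 at late ring. Ring replicate 5 was also the lowest of the 35 for Aqu2.1.35836_001 (1567 CPM) and Aqu2.1.33181_001 (1225 CPM). Of 3295 gene models with at least 50 CPM in at least 10 embryo libraries, 23 had an inner gap of at least 4-fold, and 3 of these had libraries on both sides in all 7 stages. Aqu2.1.23821_001, with a gap of 3.37-fold, was not among the 23 and was found by its opposite split. Juvenile replicate 2, which had 21359 counts, carried both Aqu2.1.23821_001, at 3137 CPM, and Aqu2.1.35836_001, at 3605 CPM. These gene models were chosen after their values were seen, and no test was made between the libraries on either side.

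**Figure D5:**
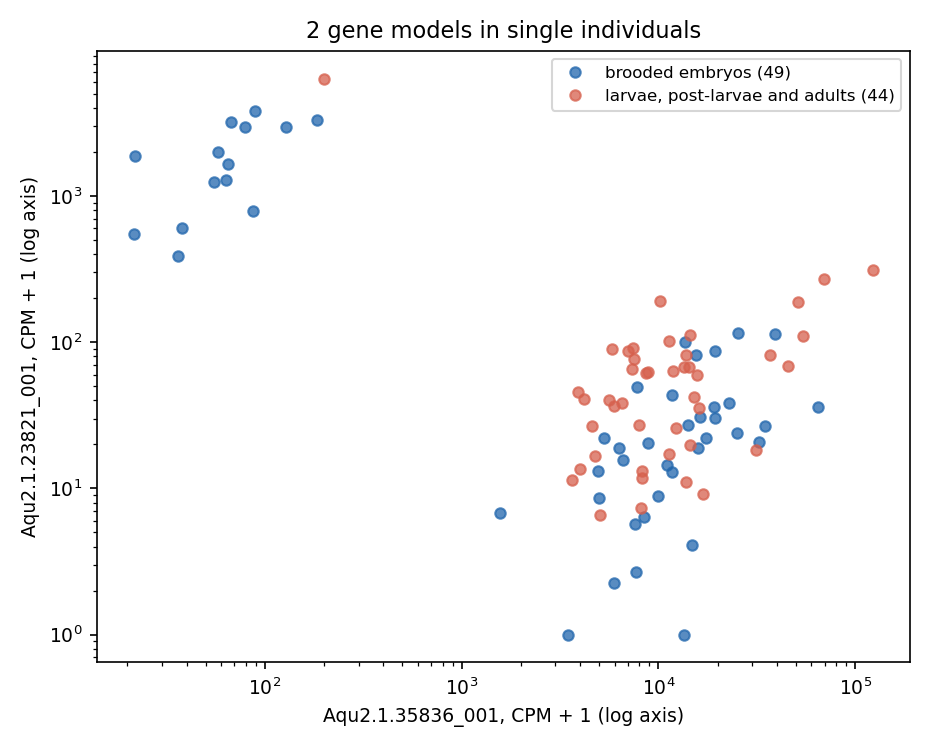
CPM of Aqu2.1.35836_001 against CPM of Aqu2.1.23821_001, each plus 1 on a log axis, with 1 point per individual for 49 embryos and 44 later individuals with at least 100000 counts. Embryos lie either at the upper left (14 individuals) or at the lower right (35), and a single later individual, juvenile replicate 5, lies at the upper left.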

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

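No test was made of these results beyond the screen for libraries that stand apart, and Aqu2.1.20225_001, Aqu2.1.31172_001 and the gene groups drawn from the libraries numbered 101 to 124 entered it only after their values were seen. In 170 screens of a measure within a stage of 4 to 10 individuals, 17 found a library far from the others of its stage. For normally distributed values 8.5 would come by chance. Some measures are CPM with zeros and several overlap within a library, so that number is only a rough guide.

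Libraries numbered as replicate 7 at spot, ring and late ring were the least like their own stages. The median rank correlation with the rest of the stage was 0.745 for spot replicate 7 (next lowest 0.799), 0.739 for ring replicate 7 (next lowest 0.792) and 0.705 for late ring replicate 7 (next lowest 0.782). The genes that fell from brown to cloud had a mean log2(CPM + 1) of 3.95 in spot replicate 7, the lowest of that stage. Ring replicate 7 was the lowest of its stage for the genes that rose at settlement (4.50) and for those that rose from settlement to mat-formation (3.17). Late ring replicate 7 was the lowest of its stage for the genes that fell at settlement (7.13) and for those that fell from settlement to mat-formation (5.74). Replicate numbers follow the order of the embryo numbers, so these are the last individuals of their stages, with embryo numbers 87 (spot), 86 (ring) and 98 (late ring), and each had the lowest total of its stage, at 375199, 437308 and 617279 counts. Ring replicate 6, with embryo number 85, had a median rank correlation of 0.806 with its stage.

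Brown replicate 1 had a median rank correlation of 0.769 with its stage, against 0.814 for the next lowest. Cleavage replicate 3 had 11400 gene models detected at 100000 counts, against 8397 for the next highest, and 3.07 CPM of Aqu2.1.00630_001, from a single count. Cloud replicate 4 was the deepest library, with 3059409 counts and 19519 gene models detected before thinning. Late spot replicate 1 was the highest of its stage for the genes that rose at settlement, at 5.54. Aqu2.1.20225_001, the gene model that dominated cleavage, reached 1910 CPM in late ring replicate 6, against 201 CPM in the next library of that stage. Aqu2.1.31172_001 reached 390 CPM in settlement replicate 4, against 189.8 CPM in the next library. In juvenile replicate 1, which had 38188 counts, the 10 most abundant gene models took 49.5% of the counts, against 16.7% in the next juvenile.

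One library had no stage label and entered no comparison. It had 23082 counts and 7477 gene models detected, and its highest rank correlation with any labelled library was 0.356.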

How the results depend on the processing

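The fits with at least 100000 counts per library, with the number set as a covariate, within the libraries numbered 1 to 100 or 101 to 124, and blocked by runs of numbers were chosen after seeing the data; the other alternatives were planned. DESeq2's size factors in the edgeR fit kept all 15 counts of genes (14 comparisons and all stages) within 1.5 times, as did a log2 fold change of at least 1 for the 14 comparisons. They shifted the median log2 fold change of all genes by between -0.0666 and 0.0615. No named gene model changed direction. The balance of genes up and down turned in some fits at brown (689 and 680, to 664 and 964 in one fit of all stages), cloud (833 and 860, to 964 and 558 without a filter), spot (109 and 128, to 81 and 77 with the covariate), settlement (356 and 393, to 608 and 467 in DESeq2), chamber-formation (9 and 0, to 2 and 551 in DESeq2), tent-pole-formation (13 and 4, to medians of 2.5 and 5 with 3 libraries), juvenile (9 and 0, to 56 and 76 without a filter) and late ring vs cleavage (1060 and 849, to 1493 and 1778 in one fit). The count over all stages stayed within 1.5 times under each alternative. The stage matches of nearest neighbours kept a permutation p of 1e-05. DESeq2's likelihood ratio test over all stages and the gene list tests (camera and fry, with either scaling or correlation) were not run, and keeping all labelled libraries became the design itself. No label pairs individuals across stages, so the only matched analysis was the block by runs of numbers given below. The cause of each shift below was not tested, except that fewer libraries or genes enter some fits by construction.

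Without a filter on low counts the called genes were 419 for spot vs cloud, 167 for late spot vs spot, 159 for ring vs late spot, 865 for free-swimming vs late ring, 3292 for settlement, 606 for mat-formation, 360 for chamber-formation, 66 for tent-pole-formation, 132 for juvenile, 865 for adult and 3137 for late ring vs cleavage. DESeq2's Wald test called 447 for spot vs cloud, 65 for late spot vs spot, 54 for ring vs late spot, 790 for late ring vs ring, 553 for chamber-formation, 2 for tent-pole-formation and 30 for juvenile. With the library total as a covariate edgeR called 809 for brown, 305 for free-swimming, 5 for chamber-formation, 0 for tent-pole-formation (239 at an unadjusted p under 0.05) and 0 for juvenile (540). One fit of all stages called 365 for cloud, 37 for spot, 7 each for late spot and ring, 156 for late ring, 2756 for settlement, 745 for mat-formation, 363 for chamber-formation, 0 for tent-pole-formation (790 unadjusted), 14 for juvenile, 170 for adult and 3271 for late ring vs cleavage.

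With at least 500000 counts per library edgeR called 359 for free-swimming, 331 for settlement, 1645 for mat-formation, 1012 for chamber-formation, 0 for tent-pole-formation (453 unadjusted) and 162 for juvenile. At settlement this fit cannot tell stage from number set. From mat-formation to juvenile it used the same libraries as the fit within those numbered 101 to 124, so it is no separate alternative. With at least 100000 counts edgeR called 467 for mat-formation, 303 for chamber-formation, 0 for tent-pole-formation and 162 for juvenile, the last 2 again from the same libraries. Within the libraries numbered 101 to 124 it called 1645, 1012, 0 and 162 for these, and within those numbered 1 to 100 it called 10 for mat-formation and 0 for juvenile (18 unadjusted). The block by run, whose numbers do not pair the individuals, gave 1496, 810, 0 and 10, and 192 for adult. With 3 libraries per stage the medians over 10 draws were 446 for brown, 148.5 for cloud, 3 for spot, 0 for late ring and free-swimming, 12 for settlement, 0 for mat-formation, 256.5 for chamber-formation, 7 for tent-pole-formation, 2 for juvenile and 1140.5 for late ring vs cleavage. Leaving out 1 replicate gave 3 to 7 for chamber-formation, 0 to 27 for tent-pole-formation, 5 to 75 for juvenile and 320 to 617 for adult, with the 617 from leaving out adult replicate 2.

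Genes highest at settlement were 863 by the median and 841 with at least 100000 counts per library, those highest at mat-formation 143 and 638, and those highest at tent-pole-formation 295 by the median. Among the named gene models, 15 fits ended the call and none turned a direction. Some of these fits used the same libraries under different settings, so fewer of them are distinct.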

Other observations

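Of the tests below, the spread of late spot against spot, the depth of the libraries low in the split gene models, the order of their embryo numbers, the summed counts of the split gene models, their share in embryos and later individuals and the splits within a number set were chosen only after the results were seen, and the comparisons within the libraries numbered 101 to 124 were added after seeing the data.

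Genes that rose during brooding were among those that fell at settlement and mat-formation more often than in independent lists. Among genes called in pairs of comparisons that share no libraries, 318 rose from brown to cloud and fell from settlement to mat-formation in the libraries numbered 101 to 124, against 93.3 common to independent lists, and 21 rose in both, against 64.2. Likewise 223 genes rose from cleavage to late ring and fell at settlement, against 95.0, and 9 fell in both, against 57.6. At chamber-formation in those libraries the direction depended on the earlier step. Of the genes that rose from brown to cloud, 124 rose there, against 41.5, and 43 fell, against 36.3. Of those that fell from ring to late ring, 48 rose at chamber-formation, against 10.2, and 3 fell, against 9.77. Of those that rose from ring to late ring, 67 fell there, against 17.9, and 7 rose, against 18.6. Also, 72 genes fell from late ring to free-swimming and rose at chamber-formation, against 22.8. At settlement 70 rose that fell at chamber-formation, against 24.1. A gene called as risen stands at a level from which it can fall, so part of an excess of rise and later fall may be built in. Genes are not independent replicates, so these are descriptions of the lists.

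Genes called in both of the first steps mostly moved the same way in both, which does not hold for all genes of either step. With the brown libraries split so that each comparison used its own, 129 genes rose both from cleavage to brown and from brown to cloud, against 24.1 common to independent lists, 33 fell in both, against 15.3, 6 rose and then fell, against 26.0, and 3 fell and then rose, against 14.2. The 860 genes that fell from brown to cloud had a mean log2(CPM + 1) of 5.72 ± 1.00 (SD, n = 7) at cleavage, 6.31 ± 0.45 (n = 7) at brown and 4.77 ± 0.15 (n = 7) at cloud, so as a group they had not fallen at the step before. Gene models with neighbouring identifiers had similar profiles over the stages, with a mean correlation of 0.292 across 4745 pairs of adjacent identifiers and 0.129 across pairs 100 identifiers apart. Whether identifier order follows the genome is not given in the sources used here.

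The gap between 80 genes called from settlement to mat-formation over all libraries and 1645 within the libraries numbered 101 to 124 was weighed as an effect of depth. Libraries of that set thinned to the totals of the libraries numbered 1 to 100 gave a median of 398 called genes over 5 draws, from 263 to 503, which argues against depth as the whole cause. The libraries numbered 1 to 100 alone gave 10 genes, at a dispersion of 1.07 against 0.168 to 0.174 in the thinned libraries. The profiles of the shallow libraries are therefore a candidate explanation. Degraded RNA, failed amplification and a wider range of ages within the mat-formation stage were not tested and stay open.

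The absence of genes called by edgeR's filtered test from spot to late spot and from late spot to ring was weighed against depth and spread. The steps were not silent in every fit, since DESeq2 called 65 and 54 genes, edgeR without a filter on low counts 167 and 159, and one fit of all stages 7 each. Late ring against ring, thinned to the totals of the late spot libraries, still gave 489 genes, which argues against depth as the whole cause. The dispersions of the quiet steps, 0.309 and 0.328, were below the 0.350 of late ring against ring, which argues against spread as the whole cause, but above the 0.272 of spot against cloud, where 237 genes were called, so a part played by spread stays open. Across both steps together, ring against spot gave 374 genes (193 up and 181 down). Slow change in the middle of brooding may describe this window, as a hypothesis found and tested on the same data. How long each stage lasts was not used here.

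The gene models with low and high states in embryos are a pattern that a sponge biologist may want to follow. The totals argue against depth as the cause, since 6 of the 14 low libraries had totals above 1030718, the median of the other embryo libraries. Pools that follow the embryo numbers were neither shown nor excluded (permutation p = 0.95 for low libraries with adjacent numbers). A sequence variant that only moves reads from the 3 gene models to Aqu2.1.23821_001 would keep their sum, and the tables argue against it. In each embryo stage the summed CPM of the 4 gene models was at least 3.60 times higher in every high library than in any low library, and at cloud the 3 summed to 64770 to 84830 CPM in the high libraries, where Aqu2.1.23821_001 reached 1252 to 3189 CPM in the low ones. A variant whose reads are mostly lost is not excluded by the sums, and it should recur after the embryo stages. Of 44 later libraries with at least 100000 counts, juvenile replicate 5 was lowest in all 3 and ranked 1 for Aqu2.1.23821_001, at 6349 CPM against 309.6 in the next, a single case. The low state was found in 14 of 49 embryos and in 1 of these 44 libraries, and in none of the 13 larvae. The gene models were chosen for their split in the embryos, which fixes a minimum share there, so Fisher's exact test of these shares (p = 0.000476) decides nothing about a variant equally frequent in both. Such a variant stays open, while reads shared between copies and on or off expression in single individuals stay untested.

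A hypothesis that adults return to genes of cleavage embryos could not be decided. The odds of rising from juvenile to adult, for genes that fell against genes that rose from cleavage to brown, gave an odds ratio of 0.510 (95% interval 0.00799 to 10.7, Fisher's exact test p = 1), and of 1.05 (0.232 to 4.83) without juveniles under 100000 counts, over 35 and 36 genes.

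Other splits of the same libraries were compared with the stage labels. The 6 comparisons with called genes among embryo and larval stages used libraries numbered 1 to 100. In these, no other split drawn called as many genes as the stage labels. That is 1 of 100 splits in each, the smallest share these draws can give. It argues against chance as the source of the whole number of calls, and says nothing about single genes. The stage labels called 1369 genes for brown, against 715 in the highest other split, 1693 for cloud (551), 237 for spot (17), 496 for late ring (1), 571 for free-swimming (57) and 1909 for late ring vs cleavage (780). For late spot vs spot and ring vs late spot the stage labels called 0 genes in edgeR's filtered test (428 and 433 at an unadjusted p under 0.05, and 65 and 54 called by DESeq2), which all 100 splits reach by construction, so these splits say nothing about chance, and the highest other splits called 4 and 6.

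From settlement onwards the stages differ in their makeup of number sets, and splits over all libraries cross the sets. Such splits reached the stage labels in 1 of 100 for settlement (749 genes, highest other 17), mat-formation (80, 14) and chamber-formation (9, 6), 1 of 56 for adult (395, 299) and 1 of 21 for all stages (12984, 5260). Splits within a set were therefore added. There 1 of 100 splits drawn reached the stage labels for settlement in the libraries numbered 1 to 100 (976 genes, highest other 65). The same held for mat-formation (1645, 2) and chamber-formation (1012, 568) in those numbered 101 to 124. This argues against chance as the source of the whole number of calls at these steps. For all stages with labels permuted within each set it was 1 of 21, the smallest share possible there. Permuted labels still called up to 6582 genes, so chance or the number sets are not excluded for a large part of the 12984. For 3 against 3 individuals the 10 splits within the set are too few for a share under 0.05, with 162 genes for juvenile (highest other 0) and 333 for adult (0). For tent-pole-formation the labels called 0 genes within the set, which all 10 splits reach by construction (highest other 1). Over all libraries 32 of 84 splits reached the 17 genes of tent-pole-formation and 29 of 100 the 9 of juvenile, so chance cannot be excluded there, and the highest splits, with 1842 and 168 genes, follow the number sets, a structure of the samples.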
